A study of Arabidopsis thaliana with 20 samples.

How the data were processed

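RNA was sequenced from 20 samples of Arabidopsis thaliana in the Col-0 background. Per the labels, 6 samples carry a transgene that overexpresses PPD3, a PsbP-domain protein of the plastid (T+), 3 of them from dwarf and 3 from normal plants. The Gen1 group, 3 dwarf samples, holds siblings of T+ plants, and its genotype label gives it without the transgene. Gen2, the progeny of Gen1, has 5 dwarf and 3 large samples, and 3 samples are wild type (WT). The series' design text gives 3 replicates per group, and all 5 samples labelled Gen2 dwarf were used. The ecotype label of WT 3 reads Col-1 where its source name and the other samples give Col-0. Per the labels' protocols, plants grew on soil at 22 and 20 °C under a photoperiod of 12 h. RNA of the aboveground tissue was purified with a NucleoSpin RNA Plant kit, and TruSeq RNA v2 libraries were read as 100-bp pairs on a DNBseq instrument to at least 4 Gb. The labels call the samples of a group biological replicates. Whether a sample is 1 plant or a pool, and whether plants shared a tray or a harvest hour, is not given in the sources used here, so p-values measure the spread between these samples.

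The deposited values are raw counts per gene and sample, as whole numbers, made by the authors from reads trimmed with Trim Galore 0.4.1 and aligned with STAR 2.7.0a to TAIR10, per the submitters' processing notes. The counting program, the annotation release, the use of strand, and whether a count is a read or a pair are not given in the sources used here. The library kit does not mark strand, so overlapping or antisense genes can share reads. Counts of reads that aligned to more than 1 place are 0 in every sample, so genes with near-identical copies are uncertain as well. Each file has 34262 genes and 5 kinds of lines without a gene. Reads without a gene came to 0.768 to 1.122% of a sample's gene counts and ambiguous reads to 0.261 to 0.356%. These lines were left out of library sizes and tests. All genes of the plastid and mitochondrial genomes are at 0 in every sample. Gene names and coordinates came from the TAIR10.1 annotation, in which 32548 of the 34262 loci were found.

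Gene counts came to between 45728485 and 117753467 per sample. Levels are given in CPM, counts scaled by edgeR to the library size. A count of 0 allows up to 3 counts, between 0.0255 and 0.0656 CPM in 1 sample. This covers counting error only. Samples of a group differed by more than sampling noise, with a chi-square per gene between 36.4 and 210.3, so each counts as 1 replicate.

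The groups, the 9 comparisons, the interaction, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Contrasts that pool groups and their alternatives, fits without 1 library for shared calls, DESeq2 and the block for calls shared against WT, the PsbP list without PPD3 and the simulation with drawn WT libraries were chosen after. Genes were kept by edgeR's filterByExpr at a minimum count of 10, which left 21703. The 20 samples entered 1 model with a term per group, in edgeR 4.0.16 under R 4.3.3, with TMM scaling (factors 0.91 to 1.05) and robust quasi-likelihood tests on 14 residual degrees of freedom. The common biological coefficient of variation was 0.225. Adjusted p-values are Benjamini-Hochberg values over all tested genes, and a gene is called at a threshold of 0.05. Errors of log2 differences are standard errors (SE), derived from the quasi-likelihood F, and those of CPM are standard deviations (SD) over the n samples of a group. Fitted differences use edgeR's defaults, with a prior count of 2 for plotted and averaged log2 CPM. Beside counts of called genes without overlap between groups stands chance, which gives 10% of genes for 3 samples against 3.

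The 9 comparisons set each of the other groups against WT, dwarf against normal plants within T+, dwarf against large plants within Gen2, Gen1 dwarf against T+ dwarf, and Gen2 dwarf against Gen1 dwarf. The difference between the dwarf effects of T+ and Gen2 was tested as an interaction. The 27 gene lists hold 553 loci, of which 552 are in the files. They cover salicylic acid defence, pattern-triggered immunity, immune receptors, jasmonate synthesis and response, ethylene response, aliphatic and indole glucosinolates (with camalexin), the nuclear-encoded photosynthetic apparatus, chlorophyll synthesis, the PsbP and PsbQ domain family, DNA methylation with RNA-directed DNA methylation, post-transcriptional silencing, flowering time and phase change, the circadian clock, cold, drought and abscisic acid (ABA) response, heat shock, expansins with xyloglucan endotransglucosylases, the cell cycle, auxin response, gibberellin and brassinosteroid pathways, oxidative stress and alternative respiration, senescence, phosphate starvation, iron homeostasis, and flavonoid and anthocyanin synthesis, with floral organ and root genes as markers of other tissues. Of the 10 root genes only 4 passed the filter, under the minimum of 5, and the list was not tested. Its highest level was 5.39 CPM (ESB1). The other 26 lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 26 lists of a comparison, and again with an estimated correlation. List counts are given over all genes tested and adjusted over the list alone. All tests were two-sided.

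PPD3 and MSH1, an organelle DNA-maintenance protein, were named in every comparison. Of the genes called without overlap of the 2 groups and with a mean log2 CPM above 1, the 5 with the largest increase and the 5 with the largest decrease were named. Up to 4 genes with the smallest adjusted p were taken from each called list, and always from the salicylic acid, jasmonate, photosynthesis, DNA methylation and floral organ lists. About 20 to 30 of these are printed per comparison, first those with the largest changes and then those of the lists in the order of the lists' adjusted p. Other genes are named only with a statement that they were chosen after their values were seen.

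The count tests were tested on simulated data with 200 changed genes before use. For T+ dwarf against WT, 41.8% of genes changed 1.5-fold, 62.7% of those changed 2-fold and 92.4% of those changed 4-fold were called, with 2.2% false calls. For Gen2 dwarf against WT these shares were 52.2, 83.6 and 97% with 5.5% false calls, and for Gen2 dwarf against Gen2 large 29.9, 85.1 and 100% with 0.7%. Alternatives were DESeq2 1.42.0, its size factors in place of TMM, no filter and a minimum count of 50, a fit of the 2 groups alone, a block for the replicate number, the estimated correlation, and fits without 1 library in turn. Size factors moved the share of higher calls by at most 5 percentage points and the median of all genes by at most 0.01 on the log2 scale. Comparisons with the same WT libraries share the chance values of those libraries. For each pair, 20 simulations drew both groups and WT from 1 mean per gene, with no effect. WT holds 3 libraries and cannot be split into sets of 2.

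Replicate numbers recur in all groups. Deviations of same-numbered samples from their group means were correlated over 0.1 in every pair only between Gen2 dwarf and Gen1 dwarf (0.12 to 0.33). There Gen2 dwarf 1, 2 and 3 each also correlated best with the Gen1 sample of their own number. This pairing comes from the values, not from the labels.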

Results

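Gene expression was measured by RNA sequencing of aboveground tissue from bolting Arabidopsis in 6 groups. These were T+ dwarf (n = 3), T+ normal (n = 3), Gen1 dwarf (n = 3), Gen2 dwarf (n = 5), Gen2 large (n = 3) and WT (n = 3). T+ plants carry the transgene, and Gen1 and Gen2 do not. Gene counts per sample were 71118082 to 82898658 in T+ dwarf, 80377820 to 89686295 in T+ normal and 89644075 to 102490446 in Gen1 dwarf. They were 45728485 to 112520877 in Gen2 dwarf, 68860129 to 103536631 in Gen2 large and 79962022 to 117753467 in WT. In a principal component analysis of the 2000 most variable genes, the first component held 25.3% and the second 15.5% of the variance. T+ normal 1 stood apart from the other samples on both, at 68.31 and −57.12, and had the fewest genes with a count, 21742.

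PPD3 (AT1G76450) encodes a PsbP-domain protein and lies on chromosome 1 of TAIR10.1 from 28684551 to 28686244, where it overlaps AT1G76460. It stood at 591 ± 189 CPM (SD, n = 3) in T+ dwarf and 700 ± 97.4 CPM in T+ normal, against 112 ± 16.1 CPM in WT. Gen1 dwarf had 99.0 ± 5.89 CPM, Gen2 dwarf 107 ± 10.8 CPM (n = 5) and Gen2 large 143 ± 8.27 CPM. The levels match the genotype labels of all 20 samples. MSH1 (AT3G24320, chromosome 3 from 8822924 to 8829728), which acts in organelle genome maintenance, was called in none of the 9 comparisons. Some of the named genes overlap another annotated gene, as PPD3 does, and are uncertain for that reason. These are CHS, F3H, UGT75C1, PPD5, PQL1, CHLM, PSAN, PSAH1, BHLH38, FRO3, EDS5, WRKY40, FRK1, EFR, BT5, OPR2, CEN2, APX5, KCS2, PLDZ2, BCAT4, MCM7, AT1G10585, AT1G04463, AT3G22142, AT5G24215 and AT3G23550. Close copies make AOC1 and AOC3, IGMT1 and IGMT2, BHLH38 and BHLH39, LHCB1.1 and CYP71A12 uncertain too.

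**Figure D1:**
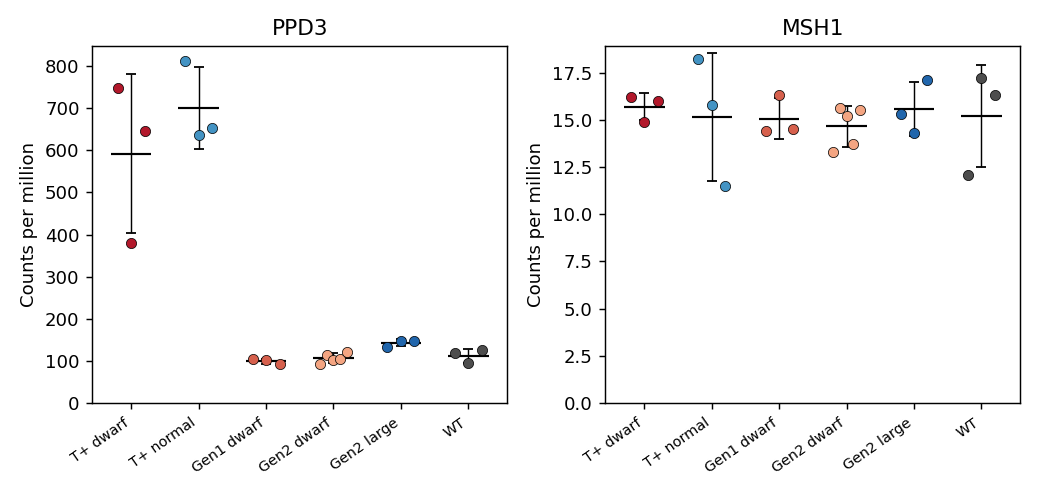
PPD3 and MSH1 in CPM (vertical axes) for each sample (points) by group (horizontal axis), with the group mean as a line and the SD as bars. All 6 T+ samples lie at or above 381 CPM for PPD3 and all others at or below 148 CPM, while MSH1 shows no such gap, with 15.2 ± 2.75 CPM in WT.

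T+ dwarf plants were set against WT to ask what differs in dwarf plants that carry the transgene. Besides PPD3, AGL19, a MADS-box activator of flowering, rose from 4.26 ± 0.364 CPM in WT to 19.9 ± 0.674 CPM (SD, n = 3 each). The log2 difference was 2.22 ± 0.31 (SE, edgeR adjusted p = 0.00412). QQS, an orphan gene that affects starch content, rose from 8.75 ± 1.57 to 39.1 ± 10.6 CPM (2.16 ± 0.28, adjusted p = 0.00214). AT3G04650 rose from 5.32 ± 0.716 to 35.1 ± 1.93 CPM (2.72 ± 0.16, adjusted p = 9.45e-09). ORC6, a subunit of the origin recognition complex of DNA replication, fell from 9.27 ± 0.4 to 5.53 ± 0.243 CPM. PPD3 itself rose by 2.40 ± 0.19 (adjusted p = 1.33e-06), and MSH1 differed by 0.05 ± 0.15 (adjusted p = 0.916). AT1G67105 also rose (3.42 ± 0.57, adjusted p = 0.0343). The RADIALIS-like gene RL4 (−1.09 ± 0.18, adjusted p = 0.0203) and AT3G46320 (−0.90 ± 0.15, adjusted p = 0.0222) fell. EdgeR called 11 genes, 7 higher and 4 lower, all without overlap between the groups. DESeq2 called 119, 42 higher and 77 lower, and 2577 genes had an unadjusted p under 0.05.

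Camera called 13 of 26 lists for T+ dwarf against WT, although PPD3 was the only member of any list called over all genes. Photosynthesis shifted down (median −0.32, 0 of 45 called, 1 lower adjusted over the list alone, adjusted p = 6.14e-11). Its members PSAN and PSAH1 of photosystem I had 466 ± 103 against 858 ± 243 CPM and 367 ± 55.2 against 519 ± 68.4 CPM. Aliphatic glucosinolates (−0.32), the cell cycle (−0.38), expansins (−0.38), flavonoids (−0.18), the PsbP family (−0.37) and chlorophyll synthesis (−0.16) also shifted down, at adjusted p from 1.81e-06 to 0.0492. Adjusted over the list alone, the PsbP family had 1 higher and 4 lower members and the other 5 lists had 0. Jasmonate (0.39), iron (0.95), immune receptors (0.19), senescence (0.58), floral organs (1.25) and post-transcriptional silencing (0.18) shifted up, at adjusted p from 2.12e-06 to 0.0168. Adjusted over the list alone, 2 iron genes were higher and 3 lower, 1 floral gene was higher and 1 lower, and the other 4 lists had 0. None of the 13 list calls held with an estimated correlation (adjusted p = 0.459 to 0.663 with an estimated correlation). Salicylic acid defence (median 0.14, adjusted p = 0.0515) and DNA methylation (−0.02, adjusted p = 0.796) were not called. Gibberellin and brassinosteroid genes and oxidative stress, also not called, had a median or mean with a sign other than that of camera.

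Calls in T+ dwarf against WT depended on single libraries. EdgeR called 6, 5 and 5 genes without T+ dwarf 1, 2 and 3, 4 without WT 1, 207 without WT 2 and 7 without WT 3, the 207 being 82 higher and 125 lower. PPD3, QQS and AT3G04650 were called in each of these fits. AT1G67105 (adjusted p up to 0.155, without WT 3), AGL19 (0.0669, without WT 1), RL4 (up to 0.182, without WT 1), AT3G46320 (up to 0.158, without T+ dwarf 1) and ORC6 (up to 0.156, without T+ dwarf 3) were not. The PsbP call ended without any 1 of the 3 T+ dwarf libraries, WT 1 or WT 3 (up to 0.414), and the chlorophyll call without any T+ dwarf library or WT 3 (up to 0.893). Those of silencing (without T+ dwarf 1 or WT 1, up to 0.142), flavonoids (T+ dwarf 2 or WT 2, up to 0.38) and expansins (T+ dwarf 1 or WT 3, up to 0.223) ended too. Without T+ dwarf 3 the calls of aliphatic glucosinolates (0.0517), floral organs (0.0517) and senescence (0.0859) ended.

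T+ normal plants were set against WT as plants with the transgene and without the dwarf phenotype. Genes of flavonoid and anthocyanin synthesis fell, 12 of 20 over all genes and 20 adjusted over the list alone (median −1.77). The list was called by camera (adjusted p = 7.74e-33, and adjusted p = 0.0199 with an estimated correlation). CHS, chalcone synthase at the head of the pathway, fell from 273 ± 94.5 CPM in WT to 78.8 ± 32.2 CPM (log2 difference −1.79 ± 0.34, n = 3 each, edgeR adjusted p = 0.0184). CHI fell from 41.5 ± 7.49 to 13.3 ± 3.9 CPM, the regulator PAP1 from 45.7 ± 7.55 to 13.0 ± 2.31 CPM, and F3H by 2.41 on the log2 scale. The flavonoid mean was lowest in T+ normal 1, the sample that stood apart (−1.72 from the mean of all libraries, against −0.81 and −0.93 in the other two). Jasmonate genes fell as well, 9 of 28 over all genes and 22 adjusted over the list alone (median −1, camera adjusted p = 2.34e-24, and adjusted p = 0.0408 with an estimated correlation). TAT3, an aminotransferase induced by jasmonate, fell from 327 ± 62.5 to 90.4 ± 24.6 CPM, and the repressor JAZ1 from 65.9 ± 8.9 to 36.6 ± 3.42 CPM. The allene oxide cyclase genes AOC1 (−1.62 ± 0.30) and AOC3 fell with them. Of single genes, AT3G04650 (3.13 ± 0.16), AT2G20670 (2.92 ± 0.39), BT2 of the BTB-TAZ family (38.2 ± 20.3 to 254 ± 89.2 CPM), PPD3 (2.64 ± 0.19) and QQS (2.55 ± 0.28) rose most. ELIP1, an early light-induced protein (−3.65 ± 0.54), RNS1, a ribonuclease of phosphate starvation (−3.25 ± 0.73), the terpene synthase TPS10 (−2.72 ± 0.57), ST2A, a sulfotransferase of hydroxyjasmonate (−2.48 ± 0.58), and the anthocyanin acyltransferase AT1G03495 (−2.46 ± 0.54) fell most. MSH1 differed by 0.00 ± 0.15 (adjusted p = 0.999). EdgeR called 290 genes, 116 higher and 174 lower, 287 of them without overlap. DESeq2 called 1156, and 3349 genes had an unadjusted p under 0.05.

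Further lists moved in T+ normal against WT. Photosynthesis shifted up (median 0.56, 1 of 45 higher, 30 adjusted over the list alone, adjusted p = 5.53e-26). RBCS2B, a small subunit of Rubisco, had 1540 ± 318 against 833 ± 170 CPM (adjusted p = 0.0482). Chlorophyll synthesis shifted up (0.48, 1 of 13, the methyltransferase CHLM, 12 adjusted over the list alone, adjusted p = 4.32e-12), and cold, drought and ABA response down (−0.61, 3 of 28, 15 adjusted over the list alone, adjusted p = 1.02e-12). These 3 calls did not hold with an estimated correlation (adjusted p = 0.0791 to 0.0827 with an estimated correlation). The caleosin gene RD20 fell from 100 ± 6.98 to 48.5 ± 6.69 CPM, and RD29B and the phosphatase HAI1 fell as well. The PsbP family shifted up (0.37, PPD3 and PPD5 of 13, 8 adjusted over the list alone, adjusted p = 3.58e-14, and adjusted p = 0.0408 with an estimated correlation, or 0.128 without PPD3). Heat shock shifted down (−0.54, HSP70 and HSP90.1 of 15, 4 adjusted over the list alone, adjusted p = 0.00148, and adjusted p = 0.0283 with an estimated correlation). Oxidative stress (−0.30, the alternative oxidase AOX1A of 19, 5 adjusted over the list alone), aliphatic glucosinolates (−0.22, 0 of 18 by either adjustment), indole glucosinolates (−0.41, 0 of 13, 1 adjusted over the list alone) and phosphate starvation (−0.42, RNS1 of 16, 2 adjusted over the list alone) shifted down at adjusted p from 0.00805 to 0.0298. Immune receptors shifted up (0.20, 0 of 21, 4 adjusted over the list alone, adjusted p = 0.000298). These last 5 stood at adjusted p = 0.251 to 0.745 with an estimated correlation. DNA methylation (median −0.03, adjusted p = 0.918), salicylic acid defence (−0.15, adjusted p = 0.995) and floral organs (−0.43, adjusted p = 0.333) were not called. Medians or means and camera differed in sign for DNA methylation, the clock and iron.

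EdgeR called 54 genes for T+ normal against WT without T+ normal 1, 463 without WT 1, 36 without WT 2 and 559 without WT 3. The split turned without T+ normal 2 (127 higher, 94 lower), T+ normal 3 (175 and 134) and WT 3 (311 and 248). Of 27 named and called genes 8 were called in each fit without 1 library, AT3G04650, AT2G20670, PPD3, QQS, ELIP1, CHI, TAT3 and RD20. The highest adjusted p was 0.254 for PPD5 without T+ normal 1. List calls ended for immune receptors (0.0546 without T+ normal 1, 0.13 without WT 1), aliphatic glucosinolates (0.0568 without T+ normal 2, 0.187 without WT 2) and oxidative stress (0.0584 without T+ normal 3). They also ended for indole glucosinolates (without T+ normal 2, T+ normal 3 or WT 2, up to 0.109) and phosphate starvation (without T+ normal 2, T+ normal 3, WT 2 or WT 3, up to 0.26).

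Gen1 dwarf plants, dwarf siblings of T+ plants without the transgene, were set against WT. Jasmonate genes rose, 14 of 28 over all genes and 25 adjusted over the list alone (median 1.22, camera adjusted p = 2.86e-28, and adjusted p = 0.0398 with an estimated correlation). JAZ1 rose from 65.9 ± 8.9 to 161 ± 16.1 CPM (log2 difference 1.29 ± 0.18, n = 3 each, edgeR adjusted p = 0.00165). JAZ8, another JAZ repressor (2.49 ± 0.40), the jasmonate oxidase JOX3 (2.04 ± 0.36) and AOC3 (1.21 ± 0.23) rose with it. Senescence shifted up (median 1.11, 5 of 19 higher, 11 adjusted over the list alone, adjusted p = 4.79e-11, but adjusted p = 0.0668 with an estimated correlation). The NAC regulator ORE1 had 18.0 ± 6.36 against 3.94 ± 1.62 CPM and SEN1 12.3 ± 2.23 against 3.95 ± 1.55 CPM, and the pheophytinase PPH rose by 0.57 ± 0.12. The alternative oxidase AOX1D (24.3 ± 9.92 against 3.22 ± 1.39 CPM), CYP94B3, which oxidises jasmonoyl-isoleucine (51.6 ± 15.5 against 6.87 ± 1.11 CPM), AT1G67105 (3.49 ± 0.57), the bHLH gene AT1G10585 (2.71 ± 0.44) and AT3G04650 (2.64 ± 0.16) rose most. GA2OX1, which inactivates gibberellin (−1.56 ± 0.37), AT1G04463 (−1.49 ± 0.28), AT3G22142 (−1.47 ± 0.32), SSL1 (−1.44 ± 0.26) and the indole glucosinolate methyltransferase IGMT2 (−1.41 ± 0.32) fell most. PPD3 (−0.18 ± 0.18, adjusted p = 0.647) and MSH1 (−0.01 ± 0.15, adjusted p = 0.977) were not called. EdgeR called 437 genes, 351 higher and 86 lower, 431 of them without overlap. DESeq2 called 1134, and 3718 genes had an unadjusted p under 0.05.

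Other lists in Gen1 dwarf against WT shifted with few single calls. Photosynthesis shifted down (median −0.46, 1 of 45 lower, 18 adjusted over the list alone, adjusted p = 3.04e-17, but adjusted p = 0.264 with an estimated correlation), the called gene being PSAH1 at 310 ± 8.4 against 519 ± 68.4 CPM. The PsbP family (−0.37, 0 of 13, 5 adjusted over the list alone), the cell cycle (−0.35, 0 of 22 by either adjustment) and chlorophyll synthesis (−0.26, 0 of 13 by either adjustment) shifted down at adjusted p from 3.33e-05 to 0.00921. They stood at adjusted p = 0.325 to 0.624 with an estimated correlation. Salicylic acid defence shifted up (0.49, 1 of 24, 3 adjusted over the list alone, adjusted p = 3.33e-05, but adjusted p = 0.414 with an estimated correlation). WRKY60 rose from 16.0 ± 1.45 to 40.6 ± 6.63 CPM. Heat shock shifted up (0.62, 0 of 15, 3 adjusted over the list alone, adjusted p = 0.00079, and adjusted p = 0.0398 with an estimated correlation). Indole glucosinolates shifted up (0.45, IGMT1 higher and IGMT2 lower of 13, 7 and 1 adjusted over the list alone, adjusted p = 0.000224), as did pattern-triggered immunity (0.34, WRKY40 of 14, 4 adjusted over the list alone, adjusted p = 0.0012). Immune receptors (0.22, 0 of 21) and iron (0.97, 0 of 16), without a call by either adjustment, shifted up at adjusted p = 0.000283 and 0.0012. The last 4 stood at adjusted p = 0.19 to 0.414 with an estimated correlation. Floral organs (median 1.48, adjusted p = 0.0631) and DNA methylation (−0.10, adjusted p = 0.0942) were not called. The median of the flavonoid list, not called, differed in sign from its mean and from camera.

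EdgeR called 159, 156 and 202 genes for Gen1 dwarf against WT without Gen1 dwarf 1, 2 and 3, 71 without WT 1, 681 without WT 2 and 232 without WT 3. AT1G67105, AT1G10585, AT3G04650, JAZ1, JAZ8 and WRKY60 were called in each such fit, and the other 16 of 22 named and called genes were not. The highest adjusted p was 0.199 for IGMT1 without WT 1. The list calls of immune receptors (0.062 without WT 1) and chlorophyll synthesis (0.0772 without Gen1 dwarf 1, 0.582 without WT 3) ended.

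Gen2 dwarf plants, progeny of Gen1, were compared with WT to ask what differs in dwarf plants a generation later. AGL19 rose from 4.26 ± 0.364 CPM (n = 3) to 16.7 ± 6.12 CPM (n = 5, log2 difference 1.97 ± 0.29, edgeR adjusted p = 0.00814). QQS had 48.7 ± 11.3 against 8.75 ± 1.57 CPM (2.47 ± 0.27, adjusted p = 0.000205), and AT3G04650 rose by 2.66 ± 0.15 (adjusted p = 5.25e-09). The peptide transporter gene PTR3 (16.9 ± 6.46 against 4.25 ± 0.804 CPM) and the centrin gene CEN2 (7.35 ± 1.13 against 2.33 ± 0.683 CPM) rose too. MYB4, a repressor of phenylpropanoid genes, fell from 18.4 ± 1.47 to 11.5 ± 1.39 CPM (adjusted p = 0.00964), and the expansin EXPA5 from 53.9 ± 2.99 to 34.0 ± 4.43 CPM (adjusted p = 0.0111). LSU2, a gene of the low-sulfur response (18.9 ± 1.08 to 11.1 ± 1.55 CPM), AT1G70640 (−1.20 ± 0.22) and OPR2 (−0.76 ± 0.14) fell as well. PPD3 (−0.07 ± 0.16, adjusted p = 0.896) and MSH1 (−0.05 ± 0.13, adjusted p = 0.907) were not called. The calls came to 21 genes, 13 higher and 8 lower, all without overlap. DESeq2 called 368, and 2833 genes had an unadjusted p under 0.05.

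Of all list members only EXPA5, of the expansin list, was called over all genes for Gen2 dwarf against WT, and camera called 12 other lists. Flavonoids shifted down (median −0.87, 9 of 20 lower adjusted over the list alone, adjusted p = 2.65e-15) and senescence up (0.81, 5 of 19 adjusted over the list alone, adjusted p = 1.3e-10). Both stood at adjusted p = 0.145 with an estimated correlation. Counts adjusted over the list alone in the other lists that shifted up were 3 of 21 for immune receptors (0.22), 6 of 28 for jasmonate (0.41), 1 of 24 for salicylic acid (0.32) and 3 higher and 1 lower of 16 for phosphate starvation (0.47). They were 2 of 9 for post-transcriptional silencing (0.18), 0 of 14 for pattern-triggered immunity (0.43) and 0 of 13 for indole glucosinolates (0.20). These 7 lists had adjusted p from 2.22e-07 to 0.0409 by camera, and adjusted p = 0.255 to 0.385 with an estimated correlation. Cold, drought and ABA response (−0.32, 1 higher and 5 lower of 28 adjusted over the list alone), photosynthesis (−0.15, 0 of 45) and the PsbP family (−0.12, 2 lower of 13) shifted down, at adjusted p from 0.000209 to 0.00433. They stood at adjusted p = 0.385 to 0.622 with an estimated correlation. JAZ1 had 103 ± 20.3 against 65.9 ± 8.9 CPM (adjusted p = 0.116). Floral organs (median 0.41) and DNA methylation (0.11) were not called, both at adjusted p = 0.525. Expansins, not called, differed in sign between median or mean and camera.

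EdgeR called 75, 36, 11, 13 and 13 genes for Gen2 dwarf against WT without Gen2 dwarf 1 to 5, and 8 without WT 1. The split turned without Gen2 dwarf 2 (14 higher, 22 lower), Gen2 dwarf 4 (6 and 7), WT 1 (2 and 6) and WT 3 (6 and 9). AT3G04650, QQS and MYB4 were called in each fit without 1 library, and the other 7 named genes were not, AGL19 reaching an adjusted p of 0.0804 and the highest 0.155, both without WT 1. List calls ended for pattern-triggered immunity (0.054 without Gen2 dwarf 5, 0.0691 without WT 1), silencing (0.143 without WT 1) and phosphate starvation (0.088 without WT 1). They ended for indole glucosinolates (without Gen2 dwarf 2, Gen2 dwarf 3, WT 1 or WT 3, up to 0.23), photosynthesis (without Gen2 dwarf 1, WT 1 or WT 3, up to 0.158) and the PsbP family (0.0727 without Gen2 dwarf 1, 0.226 without WT 3). Ethylene and iron, not called here, were called in the opposite direction without WT 2 (0.0378 and 0.00816). Iron was called in its own direction without WT 1 (4.14e-05) or WT 3 (0.0265).

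Gen2 large plants, the non-dwarf progeny of Gen1, were set against WT. Jasmonate genes fell, 8 of 28 over all genes and 19 adjusted over the list alone (median −0.83, camera adjusted p = 4.4e-23, and adjusted p = 0.0476 with an estimated correlation). AOC3 had 7.57 ± 1.26 against 20.4 ± 4.85 CPM (log2 difference −1.43 ± 0.24, n = 3 each, edgeR adjusted p = 0.0106) and TAT3 95.1 ± 39.3 against 327 ± 62.5 CPM. AOC1 (−1.65 ± 0.30) and JAZ6 (−1.12 ± 0.22) fell as well. Of the indole glucosinolate list 5 of 13 were lower, 9 adjusted over the list alone (median −0.83, adjusted p = 3.24e-12, and adjusted p = 0.0167 with an estimated correlation). Among them were the cytochrome P450 genes CYP83B1 (249 ± 22.8 against 437 ± 71.6 CPM) and CYP79B2 (26.2 ± 5.22 against 54.7 ± 15.9 CPM). Of the aliphatic list 4 of 18 were lower, CYP79F2, UGT74B1, SOT17 and FMOGS-OX1, and 11 adjusted over the list alone (−0.45, adjusted p = 1.14e-09, but adjusted p = 0.255 with an estimated correlation). AT3G04650 (3.17 ± 0.16), QQS (2.77 ± 0.28), AT1G67105 (2.74 ± 0.55), AT5G24215 (2.06 ± 0.44) and DOT3 (1.28 ± 0.29) rose most. AT4G16260 (−4.65 ± 1.02), AT3G15356 (−3.09 ± 0.55), AT3G23550 (−3.01 ± 0.56), TED6, a gene of vessel differentiation (−2.86 ± 0.59), and MDHAR, a monodehydroascorbate reductase (36.8 ± 8.19 to 5.84 ± 2.85 CPM), fell most. PPD3 stood at 143 ± 8.27 against 112 ± 16.1 CPM (0.35 ± 0.18, adjusted p = 0.376), and MSH1 differed by 0.04 ± 0.15 (adjusted p = 0.937). EdgeR called 209 genes, 26 higher and 183 lower, all without overlap. DESeq2 called 743, and 3288 genes had an unadjusted p under 0.05.

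Camera called 17 lists for Gen2 large against WT. Phosphate starvation shifted down (median −0.55, 1 of 16 lower, the transporter PHT1;4, 4 adjusted over the list alone, adjusted p = 1.32e-05, and adjusted p = 0.0476 with an estimated correlation). With 1 call over all genes each, pattern-triggered immunity (−0.34, WRKY40 of 14, 2 adjusted over the list alone), ethylene (−1.14, ERF2 of 17, 9 adjusted over the list alone), oxidative stress (−0.27, AOX1A of 19, 3 adjusted over the list alone) and heat shock (−0.39, HSFB2A of 15, 4 adjusted over the list alone) shifted down. WRKY40 fell from 17.1 ± 2.51 to 5.98 ± 1.69 CPM. With 0 calls over all genes, salicylic acid defence (−0.54, 4 of 24 adjusted over the list alone), cold, drought and ABA response (−0.33, 4 of 28), flavonoids (−0.31, 1 of 20), senescence (−0.42, 1 of 19) and iron (−0.72, 0 of 16) shifted down. These 9 lists had adjusted p from 6.59e-07 to 0.0248 by camera, and adjusted p = 0.0804 to 0.465 with an estimated correlation. Photosynthesis (0.19, 45 genes), the PsbP family (0.25, 13 genes), chlorophyll synthesis (0.23, 13 genes) and the cell cycle (0.45, 22 genes) shifted up at adjusted p from 8.19e-05 to 0.00512, with 0 members called by either adjustment. They stood at adjusted p = 0.349 to 0.465 with an estimated correlation. DNA methylation (median 0.11, adjusted p = 0.0956) and floral organs (0.22, adjusted p = 0.358) were not called. Flowering time, not called, differed in sign between median or mean and camera.

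EdgeR called 42, 10 and 13 genes for Gen2 large against WT without Gen2 large 1, 2 and 3, 326 without WT 1 and 19 without WT 2. Of 27 named and called genes only AT3G04650 and QQS were called in each fit without 1 library. The highest adjusted p was 0.256 for AT4G16260 without WT 2. List calls ended for photosynthesis (0.681 without Gen2 large 3, 0.0813 without WT 2), chlorophyll synthesis (without Gen2 large 3, WT 1 or WT 2, up to 0.162), the PsbP family (0.0813 without WT 2) and heat shock (0.0793 without WT 1). The iron call ended without Gen2 large 3 (0.0613) and without WT 2, there in the opposite direction (0.258).

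**Figure D2:**
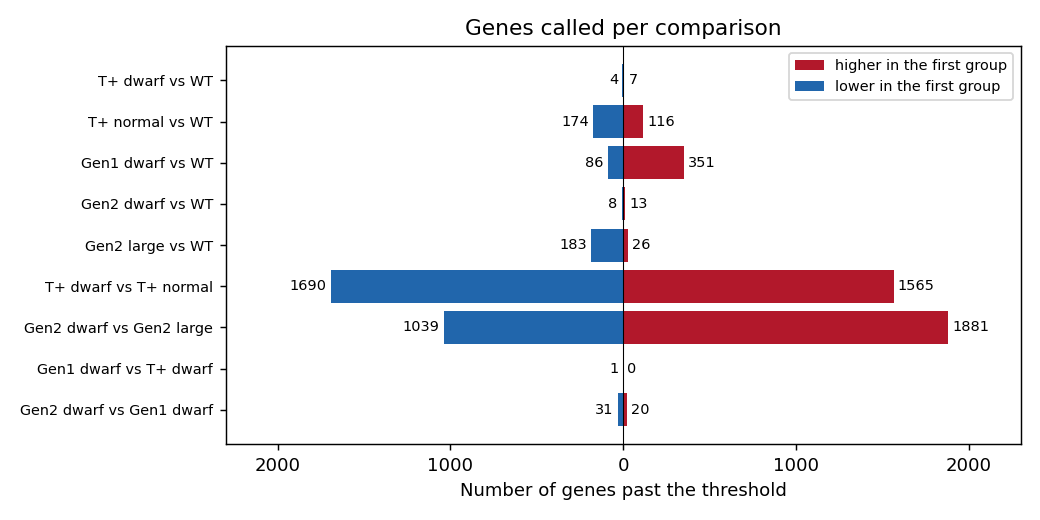
Number of genes called by edgeR (horizontal axis) as higher (bars to the right) or lower (bars to the left) in the first group of each of the 9 comparisons (vertical axis). The longest bars belong to T+ dwarf against T+ normal (1565 higher, 1690 lower) and Gen2 dwarf against Gen2 large (1881 higher, 1039 lower), while Gen1 dwarf against T+ dwarf has 1 call.

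Dwarf and normal T+ plants both carry the transgene, and their comparison asks what goes with the phenotype. Genes of photosynthesis were lower and those of jasmonate and anthocyanins higher in the dwarf plants. Of the photosynthesis list 35 of 45 were lower over all genes and 43 adjusted over the list alone (median −0.89, camera adjusted p = 3.04e-32, but adjusted p = 0.0774 with an estimated correlation). PETC of the cytochrome b6f complex had 265 ± 16.7 CPM in T+ dwarf and 629 ± 154 CPM in T+ normal (log2 difference −1.25 ± 0.19, n = 3 each, edgeR adjusted p = 0.000748). RBCS2B (−1.40 ± 0.22), PSAN and the antenna gene LHCB5 fell as well. Jasmonate genes were higher in 23 of 28 cases and 27 adjusted over the list alone (median 1.23, adjusted p = 1.35e-24, but adjusted p = 0.0657 with an estimated correlation). TAT3 had 411 ± 58.2 against 90.4 ± 24.6 CPM and the jasmonate oxidase JOX2 94.6 ± 16.4 against 22.4 ± 3.6 CPM. Of the flavonoid list 13 of 20 were higher and 16 adjusted over the list alone (median 1.5, adjusted p = 6.21e-12, but adjusted p = 0.12 with an estimated correlation). PAP1 had 62.2 ± 12.1 against 13.0 ± 2.31 CPM and DFR, dihydroflavonol reductase, 62.9 ± 9.67 against 12.9 ± 7.11 CPM, and the glycosyltransferases UGT75C1 and UGT79B1 rose with them. PPD3 differed by −0.24 ± 0.18 (adjusted p = 0.393) and MSH1 by 0.05 ± 0.15 (adjusted p = 0.862). RAP2.6, an ethylene response factor (5.02 ± 0.94), BHLH38 of the iron deficiency response (39.4 ± 19.4 against 2.33 ± 1.45 CPM), RNS1 (3.81 ± 0.74), ST2A (81.9 ± 62.1 against 6.19 ± 1.48 CPM) and the methionine sulfoxide reductase MSRB7 (3.41 ± 0.85) rose most in dwarf plants. BT2 (18.0 ± 3.35 against 254 ± 89.2 CPM), AT2G20670 (−3.81 ± 0.41), BT5 (−2.90 ± 0.55), AT5G19120 (−2.78 ± 0.41) and OXS3, a gene of oxidative stress tolerance (−2.73 ± 0.45), fell most. EdgeR called 3255 genes, 1565 higher and 1690 lower, 3149 of them without overlap. DESeq2 called 4163, and 6536 genes had an unadjusted p under 0.05.

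Smaller lists moved with these in T+ dwarf against T+ normal. The PsbP family was lower in 11 of 13 members by either adjustment (median −0.80, adjusted p = 7.82e-12, but adjusted p = 0.0774 with an estimated correlation), PPD5 at 61.7 ± 7.49 against 129 ± 29.6 CPM among them. Chlorophyll synthesis was lower in 10 of 13, 12 adjusted over the list alone (−0.60, adjusted p = 3.68e-10, but adjusted p = 0.152 with an estimated correlation), such as CHLM at 108 ± 15.5 against 224 ± 20.1 CPM. Of the cold, drought and ABA list 13 of 28 were higher, 17 higher and 1 lower adjusted over the list alone (0.74, adjusted p = 2.11e-08, but adjusted p = 0.169 with an estimated correlation), with RD20 at 163 ± 22.7 against 48.5 ± 6.69 CPM. Senescence genes were higher in 7 of 19 cases and lower in 1, NYC1 of chlorophyll b breakdown (13 and 2 adjusted over the list alone, 0.90, adjusted p = 0.000829). Indole glucosinolates were higher in 5 of 13, 6 adjusted over the list alone (0.51, adjusted p = 0.00341), with CYP71A12 at 27.5 ± 11.9 against 5.7 ± 1.93 CPM. Heat shock was higher in 4 of 15, 4 higher and 1 lower adjusted over the list alone (0.50, adjusted p = 0.0045), with HSP70 at 54.5 ± 7.72 against 13.2 ± 3.25 CPM. Iron was higher in 3 of 16 and lower in 1, the ferritin FER3 (7 and 2 adjusted over the list alone, 0.87, adjusted p = 0.0156), and floral organs higher in 4 of 12 and lower in AG (6 and 1 adjusted over the list alone, 1.83, adjusted p = 0.0156). The cell cycle shifted down (−0.42, CYCB1;4 of 22 lower, 0 adjusted over the list alone, adjusted p = 0.00743). The last 6 lists stood at adjusted p = 0.0657 to 0.594 with an estimated correlation. AP1, CAL and AP3 had 0.554 ± 0.443, 0.144 ± 0.0587 and 0.515 ± 0.347 CPM in T+ dwarf, while T+ normal lay at or near the floor. In the salicylic acid list (median 0.35, adjusted p = 0.242) 5 of 24 genes were higher, 5 higher and 1 lower adjusted over the list alone, such as the glucanase PR2 at 860 ± 349 against 400 ± 199 CPM. In the DNA methylation list (adjusted p = 0.792) 1 of 32 was lower by either adjustment, the chromomethylase CMT3 at 29.7 ± 2.0 against 41.5 ± 2.0 CPM (−0.48 ± 0.10, adjusted p = 0.00423). Not called were pattern-triggered immunity (median 0.18, adjusted p = 0.755), aliphatic glucosinolates (−0.07, 0.27), ethylene (0.16, 0.256), silencing (0.26, 0.104), flowering time (0.33, 0.104), the clock (0.03, 0.371), expansins (−0.39, 0.202) and gibberellin and brassinosteroid genes (0.02, 0.792). Oxidative stress (0.50, 0.123), phosphate starvation (0.06, 0.156), immune receptors (0.03, 0.966) and auxin (0.07, 0.966) were not called either. Immune receptors, auxin and DNA methylation had a sign in their median or mean other than that of camera.

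EdgeR called 1927 genes for T+ dwarf against T+ normal without T+ dwarf 1 and 1929 without T+ normal 1. That sample, which stood apart, had the lowest means of the flavonoid list (−1.72, against −0.81 and −0.93 in the other two) and the senescence list (−1.43, against −0.61 and −0.33). T+ dwarf 3 had the highest senescence mean, 1.15, against −0.31 and −0.18 in T+ dwarf 1 and 2. Of 59 named and called genes 41 were called in each fit without 1 library, while BHLH38, BHLH39, FRO3, MSRB7, WRKY60, PR2, EDS5, AP1, CAL, AP3, CYCB1;4 and 7 others were not. The highest adjusted p was 0.205 for PR2 without T+ dwarf 3. The calls of the cell cycle (0.189 without T+ normal 2, 0.0821 without T+ normal 3) and iron (0.0604 without T+ dwarf 3, 0.0734 without T+ normal 2, 0.0522 without T+ normal 3) ended.

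Dwarf and large Gen2 plants, both without the transgene, were compared next. Jasmonate, defence, senescence and glucosinolate genes were higher in the dwarf plants. Of the jasmonate list 24 of 28 were higher over all genes and 25 adjusted over the list alone (median 1.47, camera adjusted p = 2.67e-27, and adjusted p = 0.0274 with an estimated correlation). AOC3 had 33.4 ± 10.1 CPM in Gen2 dwarf (n = 5) and 7.57 ± 1.26 CPM in Gen2 large (n = 3, log2 difference 2.14 ± 0.23, edgeR adjusted p = 7.88e-05). TAT3 had 511 ± 160 against 95.1 ± 39.3 CPM, and JAZ1 (1.45 ± 0.17) and AOC1 (1.85 ± 0.29) rose with it. Salicylic acid defence genes were higher in 14 of 24 cases, 20 adjusted over the list alone (0.90, adjusted p = 2.06e-11, but adjusted p = 0.116 with an estimated correlation). PR2 had 1210 ± 428 against 281 ± 46.7 CPM and WRKY18 86.7 ± 12.1 against 29.1 ± 5.3 CPM. Indole glucosinolates were higher in 10 of 13 by either adjustment (1.03, adjusted p = 1.94e-11, and adjusted p = 0.0146 with an estimated correlation), with CYP79B2 at 75.7 ± 18.1 against 26.2 ± 5.22 CPM. Senescence was higher in 13 of 19, 14 adjusted over the list alone (1.32, adjusted p = 2.06e-11, and adjusted p = 0.0396 with an estimated correlation), with the NAC gene NAP (2.33 ± 0.41) and PPH (0.69 ± 0.11). PPD3 had 107 ± 10.8 against 143 ± 8.27 CPM (−0.42 ± 0.16, adjusted p = 0.0898), and MSH1 differed by −0.09 ± 0.13 (adjusted p = 0.704). PELPK1 (4.58 ± 0.97), AT2G44240 (9.2 ± 6.06 against 0.575 ± 0.16 CPM), FMO1 (6.76 ± 3.69 against 0.559 ± 0.339 CPM), MSRB7 (3.53 ± 0.79) and BFN1, a nuclease of senescence (8.16 ± 3.28 against 0.752 ± 0.0948 CPM), rose most in dwarf plants. AT1G06100 (−2.79 ± 0.79), the cutin fatty-acid hydroxylases CYP86A7 (−2.27 ± 0.57) and CYP86A4 (−2.19 ± 0.66), the proline-rich protein gene PRP2 (12.9 ± 5.17 against 60.7 ± 15.2 CPM) and AT1G09170 (−2.11 ± 0.57) fell most. EdgeR called 2920 genes, 1881 higher and 1039 lower, 2687 of them without overlap. DESeq2 called 4076, and 6545 genes had an unadjusted p under 0.05.

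Most remaining called lists of Gen2 dwarf against Gen2 large were higher in dwarf plants. Phosphate starvation was higher in 9 of 16, 10 adjusted over the list alone (median 1.11, adjusted p = 4.08e-08, and adjusted p = 0.0146 with an estimated correlation), such as PHO1;H1 (1.21 ± 0.17), PHT1;4 and PLDZ2. Heat shock was higher in 4 of 15 by either adjustment (0.67, adjusted p = 0.0026, and adjusted p = 0.0274 with an estimated correlation), such as HSP90.1 at 52.7 ± 11.4 against 25.5 ± 4.83 CPM. Aliphatic glucosinolates were higher in 10 of 18, 13 higher and 1 lower adjusted over the list alone (0.53, adjusted p = 4.32e-09), such as CYP79F2 (1.75 ± 0.26) and BCAT4. Pattern-triggered immunity was higher in 7 of 14, 10 adjusted over the list alone (0.78, adjusted p = 5.06e-07), with WRKY40 at 28.1 ± 6.86 against 5.98 ± 1.69 CPM and the receptor kinase FRK1 (1.86 ± 0.37). Immune receptors were higher in 6 of 21 by either adjustment (0.22, adjusted p = 0.000137), such as ADR1 (0.75 ± 0.13) and EFR, and ethylene in 2 of 17 by either adjustment, ERF1 and ERF2 (0.78, adjusted p = 0.0023). Oxidative stress was higher in 6 of 19 and lower in 1, the iron superoxide dismutase FSD1 (7 and 1 adjusted over the list alone, 0.41, adjusted p = 0.000731). The last 5 lists stood at adjusted p = 0.0531 to 0.347 with an estimated correlation. Photosynthesis was lower in 5 of 45 by either adjustment (−0.36, adjusted p = 4.22e-08), such as the antenna gene LHCB1.1 at 341 ± 27.0 against 648 ± 222 CPM. Gen2 large 3 had a photosynthesis mean of 0.58, against −0.04 and 0.16 in Gen2 large 1 and 2 and −0.28 to 0.01 in Gen2 dwarf. LHCB1.1 (0.0699), PSBO1 (0.233) and 2 others were not called without it. The PsbP family was lower in 4 of 13, 7 adjusted over the list alone (−0.42, adjusted p = 1.41e-06), such as PPD5 (−0.73 ± 0.14) and PQL1. The cell cycle was lower in 2 of 22, MCM5 and MCM7 of the replicative helicase, 1 adjusted over the list alone (−0.43, adjusted p = 1.06e-05), and flavonoids in 1 of 20, MYB11, 0 adjusted over the list alone (−0.54, adjusted p = 0.0126). These 4 stood at adjusted p = 0.166 to 0.584 with an estimated correlation. In the DNA methylation list, not called (adjusted p = 0.399), CMT3 (−0.30 ± 0.09, adjusted p = 0.0334) and the demethylase DML3 (−0.71 ± 0.22, adjusted p = 0.0406) were lower, 2 of 32 over all genes and 0 adjusted over the list alone. Of the floral list, not called (adjusted p = 0.742), AG of stamens and carpels was lower, by either adjustment (0.533 ± 0.228 against 1.49 ± 0.0851 CPM). Not called were also chlorophyll synthesis (median −0.16, adjusted p = 0.0916), silencing (0.13, 0.111), flowering time (0.25, 0.241), the clock (0.06, 0.533), cold, drought and ABA response (0.03, 0.367), expansins (−0.05, 0.321), auxin (0.35, 0.126), gibberellin and brassinosteroid genes (0.10, 0.367) and iron (0.17, 0.367).

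EdgeR called 1943 genes for Gen2 dwarf against Gen2 large without Gen2 dwarf 4, and 1463, 1582 and 1186 without Gen2 large 1, 2 and 3, of the last 268 lower. Of 65 named and called genes 43 were called in each fit without 1 library, while MSRB7, AT1G06100, CYP86A4, CYP86A7, PRP2, AT1G09170, LHCB1.1, MCM5, MCM7, ERF1, ERF2, MYB11, CMT3, DML3 and 8 others were not. The highest adjusted p was 0.233 for PSBO1 without Gen2 large 3. The flavonoid call ended without Gen2 dwarf 3 (0.0689) or Gen2 dwarf 4 (0.0528).

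**Figure D3:**
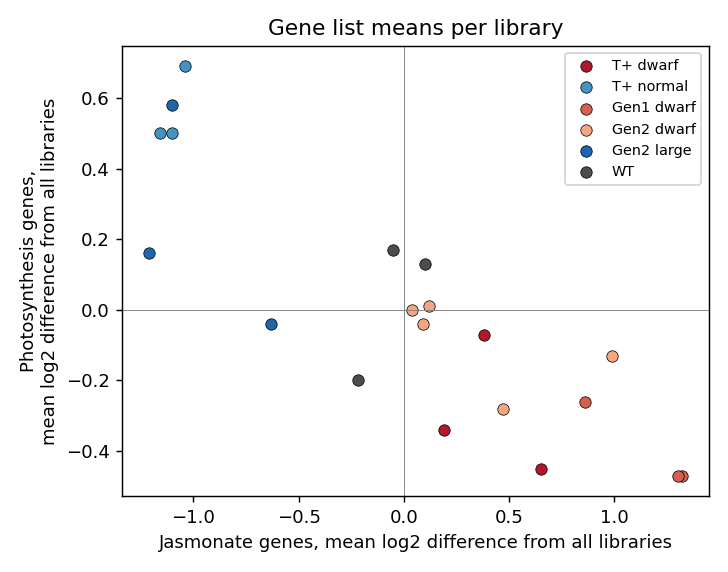
Mean log2 difference of each library from the mean of all libraries for the jasmonate list (horizontal axis) and the photosynthesis list (vertical axis), with 1 point per sample, coloured by group. T+ normal (−1.16 to −1.04) and Gen2 large (−1.21 to −0.63) lie lowest on the jasmonate axis, dwarf samples at 0.04 to 1.32 and WT between −0.22 and 0.10.

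The dwarf contrasts of T+ and Gen2, which have no library in common, shared 1127 called genes. Of these 679 were higher and 448 lower in both, where independent lists would share 135.6 and 80.9, and 27 genes were called in opposite directions. Across 17080 genes the log2 differences had a correlation of 0.52, a description across genes, which are not independent replicates. Higher in both were 21 jasmonate, 6 senescence, 5 indole glucosinolate, 4 salicylic acid and 4 phosphate starvation genes. Photosynthesis had 5, the PsbP family 4 and chlorophyll synthesis 2 members lower in both. The number of shared genes was 727, 737 and 529 without Gen2 large 1, 2 and 3, of the last 414 higher and 115 lower. The T+ contrast and Gen1 dwarf against WT, also without a shared library, had 278 calls in common, 233 higher and 45 lower in both (25.3 and 6.7 for independent lists). There 1 gene went in opposite directions, and the correlation across genes was 0.62. This number was 121, 105 and 148 without Gen1 dwarf 1, 2 and 3, 57 without WT 1, 472 without WT 2 (277 higher, 195 lower) and 136 without WT 3.

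Pairs of comparisons with the same WT libraries were set against 20 simulations per pair without any effect, which gave 0 shared calls but at most 0.05 calls per comparison on average. T+ dwarf and Gen1 dwarf shared 10 calls (0.13 for independent lists), with a correlation of 0.77 across 18274 genes (0.50 simulated) and a covariance of 0.106 (0.032 simulated). Gen1 dwarf and Gen2 dwarf shared 15 (0.24 for independent lists), with a correlation of 0.67 (0.56 simulated) and a covariance of 0.086 (0.032 simulated). T+ dwarf and T+ normal shared 5 (0.07 for independent lists), with a correlation of −0.06 (0.50 simulated) and a covariance of −0.008 (0.032 simulated). Gen2 dwarf and Gen2 large shared 4 (0.08 for independent lists), with a correlation of 0.03 (0.56 simulated) and a covariance of 0.004 (0.032 simulated). Part of the shared calls may come from the shared controls.

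Gen1 dwarf plants were set against T+ dwarf plants, their siblings with the transgene, to ask what goes with the transgene among dwarf plants. PPD3 was the only gene called, at 99.0 ± 5.89 CPM in Gen1 dwarf and 591 ± 189 CPM in T+ dwarf (log2 difference −2.58 ± 0.19, n = 3 each, edgeR adjusted p = 8.72e-07). Jasmonate genes shifted further up in Gen1 dwarf (median 0.64, 0 of 28 over all genes and 9 adjusted over the list alone, camera adjusted p = 7.27e-26, but adjusted p = 0.0526 with an estimated correlation). JAZ1 had 161 ± 16.1 against 84.4 ± 14.3 CPM (adjusted p = 0.206) and AOC3 47.4 ± 7.33 against 22.6 ± 3.54 CPM (adjusted p = 0.313). Heat shock shifted up (0.28, 0 of 15 by either adjustment, adjusted p = 0.000365, and adjusted p = 0.0203 with an estimated correlation). Senescence (0.43), aliphatic glucosinolates (0.22), salicylic acid defence (0.32), pattern-triggered immunity (0.28), auxin (0.36), indole glucosinolates (0.30) and ethylene (0.27) shifted up at adjusted p from 6.37e-06 to 0.043. They had 0 calls over all genes and 1 adjusted over the list alone, in pattern-triggered immunity, and stood at adjusted p = 0.342 to 0.485 with an estimated correlation. Photosynthesis (−0.13), the PsbP family (−0.06), DNA methylation (−0.06, adjusted p = 0.0272) and the clock (−0.09, adjusted p = 0.0462) shifted down, at adjusted p = 0.458 to 0.518 with an estimated correlation. The PsbP list holds PPD3 itself, and without it was not called (median −0.05, mean 0.03, adjusted p = 0.788). By either adjustment they had no call but PPD3. Floral organs were not called (−0.29, adjusted p = 0.403), and MSH1 differed by −0.06 ± 0.15 (adjusted p = 0.997). Flowering time, not called, differed in sign between median or mean and camera. DESeq2 called 44 genes, 41 higher and 3 lower, and 1052 had an unadjusted p under 0.05.

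PPD3 stayed called for Gen1 dwarf against T+ dwarf in each fit without 1 library, and edgeR called 10 genes without T+ dwarf 3, 9 of them higher. Camera called 8 lists without Gen1 dwarf 3 in place of 13. List calls ended for salicylic acid and photosynthesis (both 0.438 without T+ dwarf 2), DNA methylation (0.263 without T+ dwarf 1, 0.121 without Gen1 dwarf 3) and auxin (0.188 without Gen1 dwarf 3). They ended for ethylene (without T+ dwarf 1, T+ dwarf 2, Gen1 dwarf 1 or Gen1 dwarf 3, up to 0.269) and the clock (without T+ dwarf 3, Gen1 dwarf 1 or Gen1 dwarf 3, up to 0.269). Aliphatic glucosinolates lost the call without Gen1 dwarf 3 (0.264) and went the opposite way without T+ dwarf 3 (0.906). Cold, drought and ABA response was called in the opposite direction without Gen1 dwarf 2 (0.0482) and in its own without Gen1 dwarf 1 (8.81e-05).

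Gen2 dwarf plants were set against Gen1 dwarf plants, their parent generation. IMA2, a peptide of the iron deficiency response, was lower in Gen2 dwarf, at 1.79 ± 0.783 CPM (n = 5) against 18.4 ± 9.59 CPM in Gen1 dwarf (n = 3, log2 difference −3.35 ± 0.64, edgeR adjusted p = 0.0433). BHLH39 had 0.755 ± 0.128 against 12.4 ± 7.16 CPM (adjusted p = 0.049). The iron list had 2 of 16 lower over all genes and 3 higher and 12 lower adjusted over the list alone (median −1.18, camera adjusted p = 8.42e-11, but adjusted p = 0.066 with an estimated correlation). Jasmonate shifted down (−0.65, 0 of 28, 14 adjusted over the list alone, adjusted p = 6.72e-24, but adjusted p = 0.0628 with an estimated correlation), with JAZ1 at 103 ± 20.3 against 161 ± 16.1 CPM (adjusted p = 0.0922). Photosynthesis shifted up (0.31, 0 of 45 by either adjustment, adjusted p = 1.13e-15, but adjusted p = 0.265 with an estimated correlation), with PSAN at 891 ± 155 against 519 ± 139 CPM (adjusted p = 0.124). WRKY28 (3.19 ± 1.29 against 9.67 ± 2.18 CPM), AT4G02360 (−1.59 ± 0.27), KCS2, a ketoacyl-CoA synthase (−1.48 ± 0.30), AT5G52050 (−1.48 ± 0.28) and RD20 (163 ± 26.7 against 259 ± 21.1 CPM) were also lower. CYP78A8 (1.43 ± 0.27), AT5G45540 (1.36 ± 0.24), SSL1 (1.25 ± 0.24), AT5G46530 (1.1 ± 0.22) and the ascorbate peroxidase gene APX5 (1.06 ± 0.20) were higher. PPD3 (0.11 ± 0.16, adjusted p = 0.902) and MSH1 (−0.04 ± 0.13, adjusted p = 0.97) were not called. EdgeR called 51 genes, 20 higher and 31 lower, 48 without overlap. DESeq2 called 348, and 2002 genes had an unadjusted p under 0.05. With the replicate number as a block edgeR called 0 genes.

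Further lists shifted between Gen2 dwarf and Gen1 dwarf. Cold, drought and ABA response (−0.42, RD20 of 28 lower, 7 adjusted over the list alone), flavonoids (−0.67, 0 of 20, 9 adjusted over the list alone), heat shock (−0.31, 0 of 15, 1 adjusted over the list alone) and indole glucosinolates (−0.30, 0 of 13, 1 adjusted over the list alone) shifted down. So did floral organs (−0.84, 0 of 12 by either adjustment) and senescence (−0.26, 0 of 19, 1 higher adjusted over the list alone). These 6 had adjusted p from 2.32e-10 to 0.049, and adjusted p = 0.0628 to 0.504 with an estimated correlation. Chlorophyll synthesis (0.17, 2 of 13 adjusted over the list alone), aliphatic glucosinolates (0.20), the cell cycle (0.31), DNA methylation (0.14, adjusted p = 0.0012) and the PsbP family (0.12) shifted up at adjusted p from 1.14e-05 to 0.0106, with no other call by either adjustment. They stood at adjusted p = 0.313 to 0.467 with an estimated correlation. Of the 14 called lists 12 were also called with the block. Floral organs (blocked adjusted p = 0.152) and the PsbP family (0.218) were not, while salicylic acid defence (0.00346, median −0.02, 0.227 without the block), expansins (0.000784), pattern-triggered immunity (0.0301) and the clock (0.0384) were called only with it.

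EdgeR called 0 genes for Gen2 dwarf against Gen1 dwarf without Gen1 dwarf 2, 1 without Gen1 dwarf 3, and 0, 156, 6, 1 and 0 without Gen2 dwarf 1 to 5, where the 6 and the 1 were all higher. None of the 12 named and called genes was called in each such fit, the highest adjusted p being 0.537 for KCS2 without Gen1 dwarf 2. List calls ended for aliphatic glucosinolates (0.198 without Gen1 dwarf 1) and the PsbP family (0.131 without Gen2 dwarf 5). They ended for floral organs (without Gen1 dwarf 3, Gen2 dwarf 2 or Gen2 dwarf 4, up to 0.146) and senescence (without Gen1 dwarf 1, Gen1 dwarf 3, Gen2 dwarf 1 or Gen2 dwarf 2, up to 0.269).

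**Figure D4:**
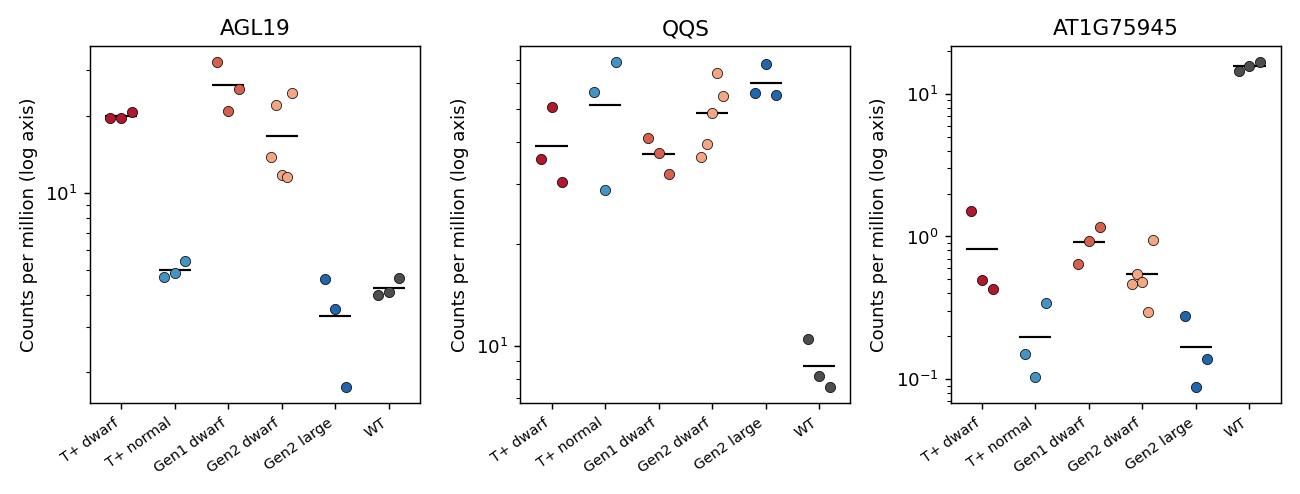
AGL19, QQS and AT1G75945 in CPM (vertical axis, log scale) for each sample (points) by group, with the group mean as a line. AGL19 lies at 11.5 to 32.3 CPM in dwarf samples and 1.76 to 5.43 CPM in all others, QQS at 7.57 to 10.5 CPM in WT and 28.9 to 69 CPM elsewhere, and AT1G75945, chosen after its values were seen, at 14.5 to 16.7 CPM in WT and 0.0884 to 1.52 CPM elsewhere.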

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

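Sample splits for comparisons other than Gen2 dwarf against Gen2 large and the interaction, all tests on the few calls against WT, and the test on single T+ normal libraries were chosen only after the result was seen.

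The dwarf effect, against normal plants in T+ and large ones in Gen2, differed for 142 genes by edgeR's interaction test (55 higher and 87 lower in T+). A difference between normal and large plants can give the same calls. Of the 142, 93 were called in T+, 76 in Gen2 and 27 in both, in opposite directions. Anthocyanin genes were higher in dwarf than in normal T+ plants and not in Gen2, with 7 of the 20 flavonoid genes called, all positive. The log2 difference between the lines was 3.34 for the acyltransferase AT1G03940 and 3.31 for AT1G03495, 3.07 for UGT79B1, 2.95 for TT7, 2.84 for DFR, 2.69 for UGT75C1, 2.44 for the transferase TT19 and 2.02 for PAP1. CER1, of wax alkane synthesis, was higher in dwarf T+ and lower in dwarf Gen2 plants (2.87). Differences the other way were −4.99 for AT2G44240, −4.38 for HSPRO2, −4.30 for AT2G20670, −4.17 for BT5, −3.93 for AT3G04640, −3.74 for BT2, −3.62 for OXS3, −3.44 for AT5G19120, −2.06 for WRKY40, −1.25 for PHO1;H1 and −0.94 for FMOGS-OX1. BT2 lay at 154 to 326 CPM in T+ normal and 13.6 to 73.2 CPM elsewhere.

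A single T+ normal library is a candidate explanation in part, since 18 genes were called without T+ normal 1, the sample that stood apart, and 47 without T+ normal 3. CER1 and AT2G20670 were called in every fit without 1 library. The other 8 genes with the largest differences were not (adjusted p up to 0.127, for AT2G44240 without Gen2 large 2). Calls also fell to 32 and 25 without T+ dwarf 1 and 2, 51 and 73 without Gen2 dwarf 3 and 5, and 24, 16 and 20 without Gen2 large 1, 2 and 3, and rose to 291 without Gen2 dwarf 1. Morning clock genes lay above evening ones by 1.03 in dwarf against normal T+ plants (0.55 in Gen2). Their interaction medians were 0.25 and 0.04 (0 called), so a different hour of harvest stays open. A low sugar state of T+ normal plants cannot be told apart, because the 20 sugar-repressed genes went both ways there (median −0.02, quartiles −0.40 and 0.34, the condition on the quartiles being added after the value was seen), 2 higher and 3 lower. In the interaction their median was −0.62 (camera p = 8.38e-09, p = 0.0552 with an estimated correlation), with 0.61 in Gen2, and against WT it was 0.31 in T+ normal and 0.26 in T+ dwarf. Of 100 drawn splits 3 gave as many calls, 142 (real), 154 and 1358. The last swaps the T+ labels and measures the sum of the effects. Mixing phenotypes widens the spread, so splits cannot decide on chance.

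In Gen2 dwarf, 18 of 306 named genes had 1 library far from the other 4, where chance gives about 1 in 20, or 15.3. These were 4, 7, 1, 2 and 4 genes in Gen2 dwarf 1 to 5.

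T+ dwarf and Gen2 dwarf had few calls against WT, 11 and 21. Low depth of the dwarf libraries is argued against, since the same libraries gave 3255 calls against T+ normal and 2920 against Gen2 large. A single WT library may account for part in T+, where 207 genes were called without WT 2, but not in Gen2, where at most 15 were. On genes of the other line the mean WT scores of −0.10 and −0.06 (SD 0.29 and 0.33) lay between dwarf and non-dwarf plants, T+ dwarf and T+ normal at 0.30 and −0.68 on the Gen2 genes, Gen2 dwarf and Gen2 large at 0.26 and −0.70 on the T+ genes. WT 2, at 0.23 and 0.31, lay within the dwarf range, and without it the means were −0.26 and −0.24, so this position of WT, found and tested on the same data, stays open for both.

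For comparisons of 3 against 3 the 10 splits are too few for a share under 0.05: the real value and the highest other were 11 and 1 (T+ dwarf against WT), 290 and 6 (T+ normal), 437 and 0 (Gen1 dwarf), 209 and 0 (Gen2 large), 3255 and 0 (T+ dwarf against T+ normal), and 1 and 0 (Gen1 dwarf against T+ dwarf). For Gen2 dwarf against WT, 3 of 56 splits gave at least the real 21 calls, up to 130, so chance stays open and the libraries have another structure. For Gen2 dwarf against Gen2 large it was 1 of 56 (2920, next 167), but splits mix phenotypes and cannot decide. For Gen2 dwarf against Gen1 dwarf, where the numbers may pair the samples, the 8 splits that part all 3 pairs are too few (real 51, highest other 0). Of all 56 splits the highest other gave 31, and the block gave 0 calls in the real one.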

How the results depend on the processing

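Fits without 1 library for shared calls, DESeq2 and the block for calls shared against WT, the PsbP list without PPD3 and all alternatives of pooled contrasts were chosen after seeing the data. Without 1 library in turn, which leaves fewer samples, the number of called genes ranged from 4 to 207 for T+ dwarf against WT, 36 to 559 for T+ normal, 71 to 681 for Gen1 dwarf, 8 to 75 for Gen2 dwarf and 10 to 326 for Gen2 large. It ranged from 1927 to 2653 for T+ dwarf against T+ normal, 1186 to 2988 for Gen2 dwarf against Gen2 large, 1 to 10 for Gen1 dwarf against T+ dwarf, 0 to 156 for Gen2 dwarf against Gen1 dwarf and 16 to 291 for the interaction. The called lists of Gen1 dwarf against T+ dwarf ranged from 8 to 17, the calls shared by T+ and Gen2 from 529 to 1223 and by T+ and Gen1 dwarf from 57 to 472, and the calls of the other groups pooled against WT from 4 to 15. DESeq2 called 119, 1156, 1134, 368 and 743 genes in the 5 comparisons with WT in that order, 44 for Gen1 dwarf against T+ dwarf, 348 for Gen2 dwarf against Gen1 dwarf and 639 for the interaction. With DESeq2, 690 calls were shared by T+ and Gen1 dwarf, and 9, 85, 221 and 23 against WT by T+ dwarf and T+ normal, T+ dwarf and Gen1 dwarf, Gen1 and Gen2 dwarf, and Gen2 dwarf and Gen2 large. A fit of the 2 groups alone, which has fewer samples, called 7, 52, 252, 4 and 119 genes in the comparisons with WT. It called 2014 for T+ dwarf against T+ normal, 0 for Gen1 dwarf against T+ dwarf and 31 for Gen2 dwarf against Gen1 dwarf, with 111 shared by T+ and Gen1 dwarf. PPD3 then passed in Gen2 dwarf against Gen2 large (−0.42, adjusted p = 0.0182) and no longer in Gen1 dwarf against T+ dwarf (−2.59, adjusted p = 0.0737). With the replicate block the counts were 7 for T+ dwarf against WT, 4 for Gen2 dwarf against WT, 1356 for Gen2 dwarf against Gen2 large, 0 for Gen2 dwarf against Gen1 dwarf and 93 for the interaction. The block left 682 calls shared by T+ and Gen2, and 6 (T+ dwarf and Gen1 dwarf) and 4 (Gen1 and Gen2 dwarf) shared against WT. In 8 of the 9 comparisons the numbers did not pair the samples, with correlations of deviations between −0.27 and 0.42. With an estimated correlation the called lists numbered 0, 4, 2, 0 and 3 against WT, 0 and 5 for the dwarf contrasts of T+ and Gen2, 1 for Gen1 dwarf against T+ dwarf and 0 for Gen2 dwarf against Gen1 dwarf. List results that reversed with a call in either fit did so without 1 library. Chlorophyll synthesis in T+ dwarf against WT had adjusted p from 0.00136 to 0.893 over these fits, the latter without WT 3 and reversed. Reversed without WT 2 were ethylene in Gen2 dwarf against WT (0.0378, with 0.971 as the highest of all fits), iron in Gen2 dwarf against WT (0.00816, in a range of 4.14e-05 to 0.535) and iron in Gen2 large against WT (0.258, with 7.73e-05 as the lowest). In Gen1 dwarf against T+ dwarf, aliphatic glucosinolates reversed without T+ dwarf 3 (0.906, with 3.17e-11 as the lowest), and cold, drought and ABA response without Gen1 dwarf 2 (0.0482, in a range of 8.81e-05 to 0.741). No named gene turned with a call in either fit. Without a call, 19 results turned without 1 library, 13 of MSH1, 2 of PPD3 (the interaction at −0.02 in place of 0.17 without T+ dwarf 1, and Gen2 dwarf against WT near 0 in place of −0.07 without WT 3) and those of BHLH39, IMA2, EBF2 and SEP3, as did 96 of lists, and in other fits 6 of MSH1 and 5 of lists. In fits without 1 library named genes had 3818 results on the same side of the threshold, 535 weaker and 64 stronger, and the lists had 1392, 82 and 80. Scaling by size factors left 641 named-gene results and weakened 1, no filter left 617 and weakened 18, and a minimum count of 50 left 599 and strengthened 6. Removing organelle genes could move nothing, since their counts are 0. Apart from fewer samples, the cause was not tested. A count of 0 allows up to 0.0656 CPM in Gen2 dwarf 2, the shallowest library.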

Other observations

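The contrasts of all dwarf samples with all others and of all other groups with WT and their genes were chosen only after the result was seen. So were the values of 3 genes by dwarf phenotype, transgene and single WT library.

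Dwarf plants of all 3 groups (11 libraries) differed from the other 9 libraries in 7125 genes by edgeR, 3867 higher and 3258 lower (9320 at an unadjusted p under 0.05). Jasmonate genes were higher in 27 of 28 cases and senescence genes in 16 of 19, and photosynthesis genes were lower in 40 of 45 and cell cycle genes in 15 of 22. Without overlap between dwarf and other samples stood 138 called genes, 97 higher and 41 lower, where chance gives 0.26 genes of all tested. AGL19 lay at 11.5 to 32.3 CPM in the dwarf samples and at 1.76 to 5.43 CPM in the others, WT included (log2 difference 2.31 ± 0.18, adjusted p = 2.03e-07). AT5G10625 (3.39 ± 0.26), AT4G33150 (1.42 ± 0.12) and AT1G72120 (0.95 ± 0.07) followed. All 4 were chosen after their values were seen, and were called in every fit without 1 library. Of 100 drawn splits only the real one gave as many calls, but another gave 5275, a sample structure. Splits mix phenotypes and cannot decide on chance.

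In 7 genes the mean of the 5 other groups differed from WT by edgeR (3 higher, 4 lower, 1563 at an unadjusted p under 0.05), 3 of them without overlap of any sample. AT3G04650 had 4.57 to 6 CPM in WT and 27.9 to 54.2 CPM elsewhere (2.86 ± 0.14, adjusted p = 5.78e-10), QQS 7.57 to 10.5 CPM and 28.9 to 69 CPM (2.41 ± 0.25, adjusted p = 0.000107), and AT1G75945 14.5 to 16.7 CPM and 0.0884 to 1.52 CPM (−5.19 ± 0.29, adjusted p = 4.2e-09). At any p, 38 genes did not overlap, 15 above and 23 below WT, where chance gives 19 each way. AT1G75945 lies on chromosome 1 from 28515245 to 28515916, 169 kb from PPD3 with 60 genes between, of which 0 were called in this contrast. The 3 without overlap, a choice that favours this, stayed called without each WT library (adjusted p up to 0.00463). A single WT library stays open for the other 4, of which 0 stayed called without WT 2 (3 of all 7). Calls numbered 13, 4 and 15 without WT 1, 2 and 3. The choice of the 3 leaves out genes limited to dwarf or transgenic plants, so it cannot test these causes. Each was called in all 5 comparisons, also in Gen2 large, which is neither (adjusted p up to 7.51e-05). Their median log2 size was 3.15 in the non-dwarf and 2.66 in the dwarf groups, and 2.77 without and 2.92 with the transgene. A difference in ancestry between WT and the transformed lines, such as a variant or an epigenetic state carried by their founder, stays untested, as does a batch that the labels do not give. Of 100 drawn splits 2 gave as many calls, 7 (real) and 748, a sample structure. Such splits mix phenotypes and cannot decide.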
